A study of Mus musculus with 8 samples.

How the data were processed

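Liver RNA from 8 male C57BL/6J mice was measured on Illumina single-colour bead arrays, 1 array per mouse. Per the labels' protocols, the mice were fed a diet with 60% of calories from fat from 6 weeks of age. After 14 weeks on that diet they were injected into the peritoneum with an antisense oligonucleotide (ASO, a short synthetic strand that lowers the RNA it pairs with) at 25 mg/kg, 2 times a week for 3 weeks. A group of 4 mice received an ASO directed against Mogat1, and 4 received a scrambled control ASO. Every mouse is listed with an age of 25 weeks, which is more than this schedule adds up to. RNA was amplified linearly with T7 polymerase and labelled with biotin, per the labels' protocols.

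The deposited table of non-normalized values gives, per the file headers, a signal intensity and a detection p-value for each of 45281 probes on each array. The detection p-value in the deposited table was read as the share of negative control beads at least as bright as the probe, which is the usual meaning of that column. The deposited series table holds a processed intensity for the same probes. Its columns had medians of 5.75 to 5.78 and 38.0% to 38.1% of values below 0, so the processed intensity is on a linear scale with background subtracted, while the software the authors used is not given in the sources used here. It was used only as an alternative. Arrays have no counting depth, so the number of mice limits the precision. The median signal per array was 84.3 to 112, and 15788 to 16944 probes were detected at p under 0.05. No pair of arrays was identical: the rank correlation of signals between arrays was 0.910 to 0.925.

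Signals were background-corrected by normexp with the negative control distribution inferred from the detection p-values, quantile normalized and brought to log2 with an offset of 16, by the neqc function of limma 3.58.1 in R 4.3.3. Values were read with the data.table package (version 1.17.8), symbols were matched in Python 3.11.15 and figures were drawn with matplotlib 3.10.9. The 16487 probes detected at p under 0.05 on at least 4 of the 8 arrays were tested with lmFit and eBayes (with a trend of variance on level), two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. A gene with several tested probes was represented by the probe with the highest mean over all 8 arrays, which gave 11686 genes. A fold is 2 to the power of the difference in normalized log2 level, with the standard error (SE) of the fit given on the log2 scale. For a probe not detected on any array of a group, the fold is given as a lower bound: the mean of the bright group is set against the mean of, per array, the higher of the probe's own level and the lowest level among detected probes. Such bounds are written "at least" and hold only for the background correction and offset used. Folds of dim probes depend on the background correction and on the offset, and are smaller without the correction or with a larger offset.

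Symbols in the array file were updated through the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the probes, 27740 carried a current symbol, 8037 were updated, 122 matched several genes and 9382 were not matched and kept the name in the file. Glutathione S-transferases of the alpha class, major urinary proteins and the Cyp families have near-identical copies, so values of single members are uncertain.

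Before the data were examined, 40 gene lists were fixed for pathways, cell types and responses that fit liver, fat feeding and ASO treatment. The 39 lists with at least 5 measured members were tested with camera (limma), which compares a list with all other genes, with a preset inter-gene correlation of 0.01, a two-sided test and Benjamini-Hochberg adjustment over the lists. "Called" below means past the threshold in this test. Camera with an estimated correlation, fry, which asks whether a list moves one way on balance, and an exact permutation test of the mean standardized level per array were run beside it. The exact test has 70 assignments of the 8 arrays, so its smallest two-sided p is 0.0286, and the smallest adjusted over the lists was 0.139. Named genes were fixed by rule: Mogat1, Mogat2, Dgat1 and Dgat2, the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap (clone and locus identifiers left out), and up to 4 members of each list past the threshold, by size of change, filled to 2 with the brightest members where fewer passed.

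The steps were tested on simulated data for this comparison with 20036 probes tested. Of the changed probes tested, 27.7% were recovered at 1.5-fold, 66.2% at 2-fold and 89.1% at 4-fold, with 6 false calls among 126. A list shifted by design was called, and 0 of 39 random lists were. That simulation drew probes independently of each other, so it says nothing of lists whose genes vary together. Beside the shifted list it changed only 67, 67 and 66 probes at these folds, while 2078 probes passed the threshold in the data. The recovery rates depend on that share and need not hold for this comparison. The alternatives were no background correction, median scaling, cyclic loess, the deposited processed values, an offset of 50, no filter, detection at p under 0.01 on all 8 arrays, other variance models, array weights, the mean of all probes of a gene, the replicate number as a block, other thresholds and leaving out each array in turn. Array numbers name different mice and were not taken as a pairing. The BeadChip of each array is not given in the sources used here, so a chip effect was not modelled.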

Results

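The liver transcriptome of obese mice given an ASO against Mogat1, which encodes an enzyme that makes diacylglycerol from monoacylglycerol, was compared with that of mice given a scrambled ASO. The largest rise was in Gsta1, a glutathione S-transferase, which was 23.4-fold higher in Mogat1 ASO livers (log2 difference 4.55, SE 0.75, n = 4 each, adjusted p = 0.0037). Gsta2 rose 7.88-fold (SE 0.55 on the log2 scale, adjusted p = 0.0061). The largest fall was in Obp2a, a lipocalin that the array lists as Lcn13, which was 30.6-fold lower (log2 difference -4.93, SE 0.14, adjusted p = 1.2e-08) and was detected on 2 of the 4 Mogat1 ASO arrays. Cyp17a1, a steroid hydroxylase, was 8.45-fold lower (SE 0.39 on the log2 scale, adjusted p = 9.8e-04). In all, 1549 of 11686 genes passed the threshold, 834 higher and 715 lower, with a median fold of 1.501. Among these, 118 were at least 2-fold higher and 92 at least 2-fold lower. The groups did not overlap for 19.1% of tested genes, where chance gives 2.86%. Leaving out 1 array gave 886 to 2261 genes past the threshold, and array weights gave 2610. The fold of Gsta1 was 38.7 without Mogat1 ASO replicate 1, 36.1 without control ASO replicate 4, 14.5 without background correction and 12.95 with the mean of its probes, that of Gsta2 was 12.2 without Mogat1 ASO replicate 1, and without background correction Obp2a was 9.86-fold and Cyp17a1 5.13-fold lower (Obp2a 16.95-fold with an offset of 50).

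The targeted transcript was not above background on any array. The single Mogat1 probe had a lowest detection p of 0.814 over the 8 arrays, and its mean log2 level was 4.42 ± 0.01 in control livers and 4.43 ± 0.05 in Mogat1 ASO livers (SD, n = 4 each, exact permutation p = 0.714). The knockdown could therefore not be read from these arrays, and no fold is given. Of 2 probes for Mogat2, another monoacylglycerol acyltransferase, 1 was detected on 1 array and 1 on none. Dgat1 and Dgat2, which make triglyceride from diacylglycerol, did not pass the threshold: Dgat1 differed by -0.41 (SE 0.12, adjusted p = 0.054) and Dgat2 by -0.19 (SE 0.10, adjusted p = 0.256) on the log2 scale. Array brightness was similar in the groups: the median signal was 100.7 ± 11.97 (SD, n = 4) in control livers and 98.6 ± 9.98 (SD, n = 4) in Mogat1 ASO livers (exact two-sided permutation p = 0.8286). Probes detected numbered 16205 ± 460 (SD, n = 4) and 16467 ± 488 (SD, n = 4), with an exact permutation p = 0.457.

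Other genes among the 10 largest rises were Avil, which encodes the actin-binding protein advillin and was not detected in any control liver (at least 4.55-fold higher, adjusted p = 0.0012), and the tumour necrosis factor family member Tnfsf14, also undetected in controls (at least 3.34-fold higher, adjusted p = 0.0059). Genes were ranked by the fitted difference. The bound for Tnfsf14 lies below the 4.16-fold rise of Cxcl10, the smallest of the 10, so its place among them is not settled. Adam32 rose 5.16-fold (SE 0.18, adjusted p = 9.8e-05). Aqp4, a water channel, rose 4.64-fold (SE 0.31), Tnnc1, a troponin, 4.39-fold (SE 0.25) and Esm1, a proteoglycan of endothelial cells, 4.20-fold (SE 0.44). Without background correction the folds were 2.72 for Avil and 2.06 for Tnfsf14 (3.79 and 2.77 with an offset of 50), below the bounds given, 3.33 for Adam32, 3.07 for Aqp4, 2.76 for Tnnc1 and 2.57 for Esm1. The call for Esm1 ended under robust variance estimation (adjusted p = 0.0574). Among the largest falls, the pseudogene Serpina4-ps1 was not detected in any Mogat1 ASO liver (at least 9.02-fold lower, adjusted p = 3.4e-04). Synj2bp, Immp2l and Rtn4ip1, whose products lie in mitochondria, were 5.06-fold, 5.03-fold and 4.21-fold lower (SE 0.18, 0.20 and 0.13). Lrtm1 was 5.94-fold lower (SE 0.34), the kinase gene Aatk 5.21-fold (SE 0.22) and Pdzrn3, detected on 3 of the 4 Mogat1 ASO arrays, 5.07-fold (SE 0.33). Without background correction Serpina4-ps1 was 3.70-fold lower (5.86-fold with an offset of 50), below the bound given, Lrtm1 3.52-fold, Pdzrn3 2.89-fold and Rtn4ip1 2.75-fold.

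**Figure D1:**
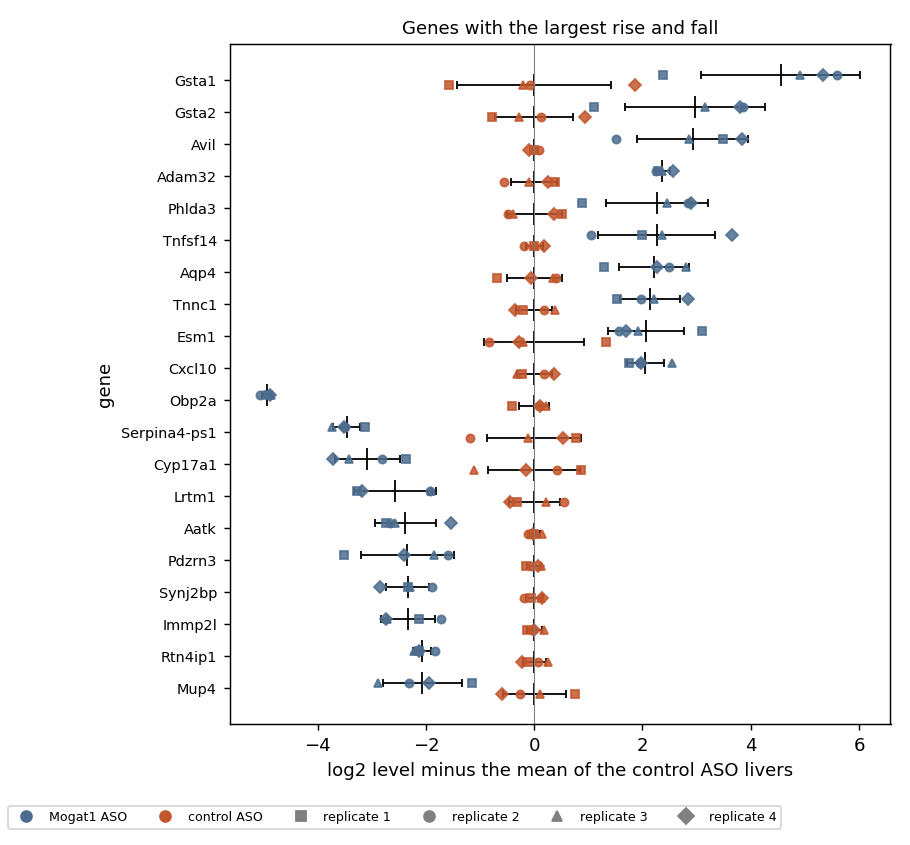
Log2 level of the 10 genes with the largest rise and the 10 with the largest fall, each minus the mean of the 4 control ASO livers. Points are arrays, shaped by replicate number, and bars are the mean and SD of 4 arrays; Obp2a lies farthest below 0 with a difference of -4.93 and Gsta1 farthest above with 4.55.

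Genes of the interferon response were higher in Mogat1 ASO livers. Of 29 measured members, 19 rose and none fell (25 rose adjusted over the list alone), with a median log2 difference of 0.80. Cxcl10, a chemokine that draws T cells, rose 4.16-fold (SE 0.19, adjusted p = 2.5e-04). The interferon-induced Ifit3 rose 3.06-fold (SE 0.15), the transcription factor Irf7 2.84-fold (SE 0.20) and Usp18, a regulator of interferon signalling, 2.77-fold (SE 0.13). Camera gave an adjusted p = 3.2e-16 with the preset correlation and an adjusted p = 0.211 with an estimated correlation. All 4 Mogat1 ASO arrays lay above all 4 control arrays in the mean level of the list (exact permutation p = 0.0286, the smallest the design allows). Adjusted over the lists, the exact p was 0.139. Several other lists reached the same exact p, the uncalled bile acid and gluconeogenesis lists among them, so full separation does not set the interferon list apart.

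Antigen presentation genes and inflammatory chemokines moved the same way. Of 16 antigen presentation genes, 9 rose and none fell (14 rose adjusted over the list alone), among them the class II genes H2-Eb1 (1.93-fold, SE 0.19) and H2-Ab1 (1.77-fold, SE 0.18) and their partner Cd74 (1.68-fold, SE 0.14). Camera gave an adjusted p = 2.6e-07, and an adjusted p = 0.211 with an estimated correlation. Of 22 cytokine and chemokine genes, 12 rose and 1 fell (16 and 2 adjusted over the list alone). The neutrophil attractant Cxcl1 rose 2.61-fold (SE 0.21), the interleukin 1 antagonist Il1rn 2.51-fold (SE 0.20) and Cxcl9 2.26-fold (SE 0.19); the fold of Il1rn was 1.55 without background correction. Camera gave an adjusted p = 4.9e-07 for this list, and an adjusted p = 0.211 with an estimated correlation.

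Markers of macrophages also rose in part, while those of other leukocytes mostly did not pass. Of 30 macrophage and Kupffer cell markers, 8 rose and 1 fell (10 and 1 adjusted over the list alone). Ms4a7 rose 2.22-fold (SE 0.19, adjusted p = 0.0035), the lectin Lgals3 1.91-fold (SE 0.18) and the Fc receptor subunit Fcer1g 1.67-fold (SE 0.12), while the scavenger receptor Cd163 was 2.02-fold lower (SE 0.20, adjusted p = 0.0077). The list had an adjusted p = 6.1e-04, and an adjusted p = 0.519 with an estimated correlation. Its mean standardized level on Mogat1 ASO replicate 1 was 0.03, inside the control range of -0.84 to 0.06. Of 16 markers of T, B and NK cells 1 rose, Coro1a (1.49-fold, SE 0.10), and of 9 neutrophil and mast cell markers none passed; neither list was called (adjusted p = 0.312 and 0.775). The median log2 difference was 0.13 and 0.03 in these lists.

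The list of genes with male-biased expression or dependence on growth hormone was lower in Mogat1 ASO livers. It holds growth hormone pathway genes such as Igf1 and Igfals beside genes higher in male liver, and is named male-biased below. Serpina4-ps1, given above, was among the members that fell. Of 27 measured, 11 fell and none rose (14 fell adjusted over the list alone), with a median log2 difference of -0.63. The major urinary protein gene Mup4 was 4.20-fold lower (SE 0.35, adjusted p = 0.004), the serpin gene Serpina12 4.08-fold (SE 0.23, adjusted p = 6.0e-04) and the fatty acid elongase gene Elovl3 3.17-fold (SE 0.25, adjusted p = 0.0025). Camera gave an adjusted p = 3.2e-07, and an adjusted p = 0.472 with an estimated correlation. The mean standardized level of the list on Mogat1 ASO replicate 1 was 0.28, inside the control range of 0.22 to 0.90, against -0.92 to -0.47 on the other 3 Mogat1 ASO arrays. The female-biased list was not called (9 measured, 2 fell and none rose, 1 higher and 2 lower adjusted over the list alone, median log2 difference -1.05, adjusted p = 0.0758). That median was as small as -0.59 over the background, scaling, source and offset settings.

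Pericentral genes, expressed around the central vein, were lower as well. Of 19 measured, 7 fell and none rose (9 fell adjusted over the list alone). The glutamate transporter Slc1a2 was 2.76-fold lower (SE 0.18, adjusted p = 9.2e-04) and Cyp1a2 1.62-fold (SE 0.13, adjusted p = 0.0074). The list had an adjusted p = 9.6e-05, and an adjusted p = 0.211 with an estimated correlation. Of 18 periportal genes, 1 rose, Aldh1b1 (2.42-fold, SE 0.20), and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.079 for the list). The median log2 difference was -0.31 in the pericentral and -0.31 in the periportal list, so the medians show no contrast between the zones, and the periportal list was called under some alternatives.

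Targets of p53, genes of the NRF2 response to oxidative stress, cell cycle genes and ribosomal protein genes were called as higher with the preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.472, 0.574, 0.574 and 0.472). Of 20 p53 and apoptosis genes 5 rose and none fell (9 rose adjusted over the list alone), among them Phlda3 (4.82-fold, SE 0.40, detected on 2 of the 4 control arrays, 2.31-fold without background correction and 3.21-fold with an offset of 50) and the apoptosis gene Bax (1.72-fold, SE 0.16). The cell cycle inhibitor gene Cdkn1a rose 3.72-fold (SE 0.44, adjusted p = 0.0173). Its call ended without control ASO replicate 3 (adjusted p = 0.0578), Mogat1 ASO replicate 3 (0.0551) or Mogat1 ASO replicate 4 (0.0564), and under robust variance estimation (0.0776). The p53 list had an adjusted p = 5.4e-04, and an adjusted p = 0.472 with an estimated correlation. Of 20 NRF2 genes 5 rose and none fell, the same counts adjusted over the list alone, including the haem oxygenase gene Hmox1 (1.74-fold, SE 0.16). The NRF2 list had an adjusted p = 0.0355, and an adjusted p = 0.574 with an estimated correlation; Mogat1 ASO replicate 1 had a mean standardized level of -0.36, inside the control range of -0.69 to 0.16. This call ended without control ASO replicate 1 (adjusted p = 0.0555), Mogat1 ASO replicate 2 (0.0908) or Mogat1 ASO replicate 4 (0.0646), with the mean of all probes of a gene (0.0563) and under fry (0.0907).

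Of 23 cell cycle genes 5 rose and none fell, the same counts adjusted over the list alone. These included the replication helicase gene Mcm6 (1.63-fold, SE 0.11) and the tubulin gene Tubb5 (1.73-fold, SE 0.13), and the list had an adjusted p = 0.0011, and an adjusted p = 0.574 with an estimated correlation. The mean standardized level of the cell cycle list on Mogat1 ASO replicate 4 was -0.21, inside the control range of -0.83 to 0.08 (exact permutation p = 0.0571). Of 33 ribosomal protein genes 16 rose and none fell (23 adjusted over the list alone), among them Rpl22 (1.45-fold, SE 0.11). The ribosomal list had an adjusted p = 5.2e-10, and an adjusted p = 0.472 with an estimated correlation.

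The count of called lists was 10 of 39, and none was called with an estimated correlation. With the preset correlation, 21 of the 35 splits of the 8 arrays into 4 and 4 called at least 10 lists, among them 8 of the 18 with 2 arrays of each group on either side, so the number of calls does not set the real groups apart.

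**Figure D2:**
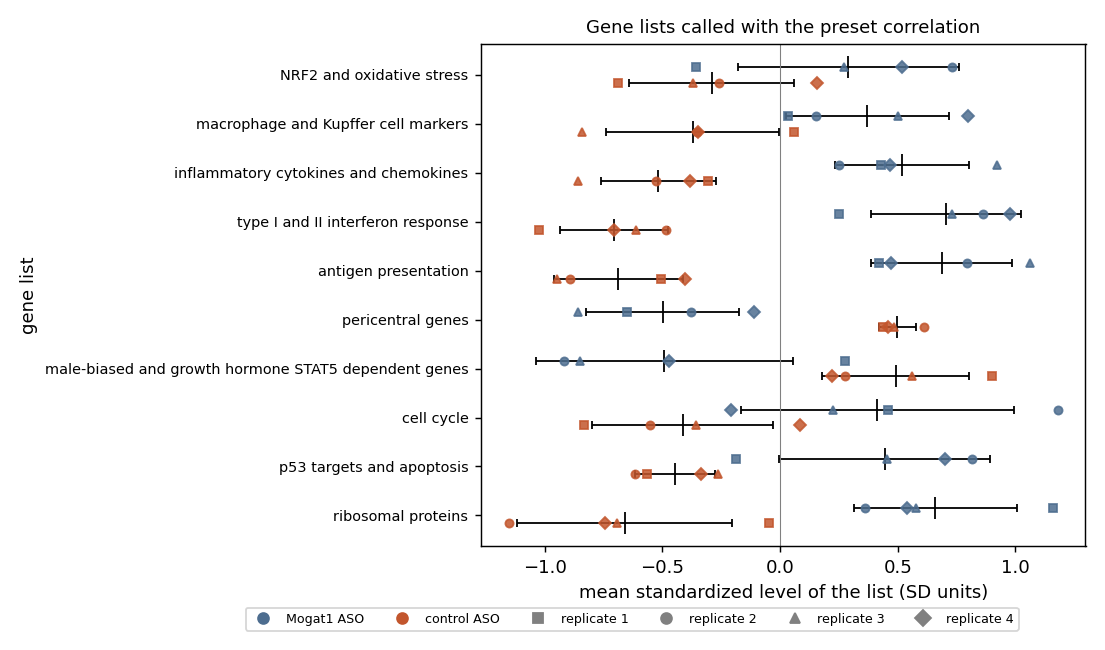
Mean standardized level of each of the 10 called gene lists, in SD units, on each array. Points are arrays, shaped by replicate number, and bars are the mean and SD of 4 arrays; for the interferon list the control arrays lie at -1.02 to -0.48 and the Mogat1 ASO arrays at 0.25 to 0.98.

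Lists for lipid and glucose metabolism were not called with the settings used here, although single members changed; the PPAR-alpha list was called under some alternatives. In the glycerol-3-phosphate pathway of triglyceride synthesis, Agpat2, an acyltransferase of that pathway, was the 1 of 18 genes that passed (1.60-fold lower, SE 0.12, adjusted p = 0.0045; adjusted p = 0.394 for the list). Of 17 genes of fatty acid synthesis, 1 rose and 2 fell (3 and 5 adjusted over the list alone, adjusted p = 0.312 for the list). Of 36 PPAR-alpha targets and genes of fatty acid oxidation, 2 fell and none rose: the acyl-CoA thioesterase gene Acot1 (3.65-fold, SE 0.29, adjusted p = 0.0027) and Eci2 (1.498-fold, SE 0.11). That list had an adjusted p = 0.0961. Of 19 PPAR-gamma targets and lipid droplet genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone, adjusted p = 0.738 for the list). The falls were the droplet proteins Plin4 (2.70-fold, SE 0.30) and Plin5 (2.08-fold, SE 0.20). The rises were Lpl (1.88-fold, SE 0.22), Hilpda (1.47-fold, SE 0.16) and Abhd5 (1.31-fold, SE 0.10). The calls for Lpl and Hilpda ended under some alternatives.

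Of 18 genes of gluconeogenesis and glycogen metabolism, 2 rose and 2 fell (adjusted p = 0.206 for the list). G6pc, the catalytic subunit of glucose-6-phosphatase, was 2.19-fold lower (SE 0.24, adjusted p = 0.0119), and the glycogen branching enzyme gene Gbe1 was 1.77-fold higher (SE 0.17, adjusted p = 0.0103). Of 21 genes of bile acid synthesis and transport, 7 fell and none rose (7 and 1 adjusted over the list alone), with Baat, which joins bile acids to amino acids, 1.57-fold lower (SE 0.12) and the co-receptor gene Klb 1.54-fold lower (SE 0.13). Camera did not call this list (adjusted p = 0.108), whereas fry did (adjusted p = 0.0045). None of 17 genes of insulin signalling passed (adjusted p = 0.556 for the list). In the other metabolic lists here the counts adjusted over the list alone were the same.

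Lists for injury, scarring and liver cell identity were not called with the settings used here, though the injury and hepatocyte lists were under some alternatives. Of 29 injury and hepatokine genes 5 rose and none fell (6 and 0 adjusted over the list alone, adjusted p = 0.0758 for the list), including Lgals3 and Cdkn1a given above. Of 31 genes of stellate cell activation and fibrosis, 3 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.312 for the list), with the matrix protein gene Sparc 1.63-fold higher (SE 0.15). Of 30 acute phase genes 3 rose and 5 fell (6 and 6 adjusted over the list alone, adjusted p = 0.988), with Apcs 1.94-fold higher (SE 0.16) and Cebpd 1.68-fold lower (SE 0.12). None of 22 hepatocyte identity genes passed (adjusted p = 0.0758, median log2 difference -0.13).

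**Figure D3:**
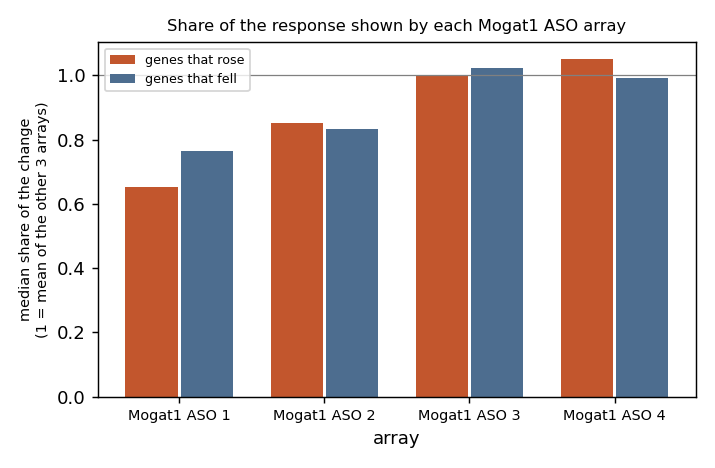
Median share of the group change shown by each Mogat1 ASO array, over genes called at least 2-fold without that array, for genes that rose and genes that fell. A share of 1 equals the mean of the other 3 Mogat1 ASO arrays; Mogat1 ASO replicate 1 shows 0.65 for genes that rose and 0.76 for genes that fell.

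Mogat1 ASO replicate 1 stood apart from the other Mogat1 ASO arrays. The first principal component, with 43.8% of the variance, placed it at 8.36, between the control arrays (-25.8 to -16.7) and the other Mogat1 ASO arrays (23.6 to 29.2). On the second component it lay at 34.4, outside the range of -15.7 to 13.9 of all other arrays, so it was not simply intermediate. The 13.9 belonged to control ASO replicate 1, and the remaining arrays lay at -15.7 to -0.08. In the PPAR-alpha list control ASO replicate 1 (-1.05) and Mogat1 ASO replicate 1 (-1.26) had the lowest mean standardized levels. The combined adipocyte, pancreas, erythroid and muscle list did not join them (-0.29 and 1.31). A cause shared by these arrays was not tested. Without it, 2261 genes passed the threshold in place of 1549, with 1467 of the 1549 kept.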

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

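All tests of explanations given here, except those over splits and over processing settings, were chosen after the results were seen. Aatk, which fell as a group, stood at a log2 level of 9.97 on Mogat1 ASO replicate 4 while the other 3 Mogat1 ASO arrays lay at 8.76 to 8.93, a gap of 0.861 of the range. This was 1 of 70 groups examined, and chance gives about 1 in 20.

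The number of genes past the threshold was set against other splits of the arrays. Only 1 of the 35 splits into 4 and 4, the real one, gave as many as 1549 genes, and the highest of the others gave 8. The other splits mix the groups, so a group difference adds to their spread and lowers their counts. The real split can rank no better than 1 in 35, so this count sets the real groups apart but does not exclude chance. For the number of called gene lists chance cannot be excluded: 21 of the 35 splits gave at least the 10 of the real split, and the highest of the others gave 20. Of the other splits, 16 set 3 arrays of a group against 3 of the other and so hold part of the treatment contrast, while among the 18 with 2 arrays of each group on either side 8 gave at least 10 lists, with a highest of 18.

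The rise of interferon response genes was set against 2 technical explanations. If more leukocytes of all kinds in the tissue were the cause, leukocyte markers would have risen at least as much. The 55 macrophage, lymphocyte, neutrophil and mast cell markers, none of them in the interferon, antigen or chemokine lists, had a median log2 difference of 0.22 against 0.80. Of the 55, 9 rose past the threshold. The gap between the mean levels of these sets was larger in all 4 Mogat1 ASO arrays (difference 0.59, exact permutation p = 0.0286). These values argue against a rise of all these cell types together. A pooled median dilutes a rise in a single cell type, and the macrophage list alone had a median of 0.33, so a rise in macrophages alone was not excluded. Normalization or background correction is also argued against, since the lowest median over 5 such settings was 0.63. An effect of the Mogat1 ASO, through its target or as an oligonucleotide, may account for the rise and stays open as a hypothesis. Macrophage activation without a change in cell number was not tested.

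The fall of male-biased genes remains less settled. A lower share of hepatocytes would lower hepatocyte genes alike, and the 22 identity genes had a median log2 difference of -0.13 (SD over genes 0.23) against -0.63. The per-array difference between the lists did not pass (exact permutation p = 0.0571), because Mogat1 ASO replicate 1 overlapped the controls, so a part from hepatocyte share cannot be told apart from regulation. A shift toward the female pattern would raise female-biased genes, whose median was -1.05 (-1.05 to -0.59 over the background, scaling, source and offset settings). Of these, 0 of 9 were higher over all genes tested and 1 was higher adjusted over the list alone. The exact permutation test of their mean level, which ran lower, did not pass (p = 0.0571). The measured list as a whole thus showed no rise, though the bound set for excluding such a shift was not met. Hepatocyte share therefore stays open, beside an effect of the treatment. With 9 of 26 fixed female-biased genes measured, a shift in part of the female pattern was not excluded.

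Mogat1 ASO replicate 1 showed a weaker response than the other 3 in the median, though not in every gene. A control liver under the wrong label is argued against: its median share of the change was 0.65 for genes that rose and 0.76 for genes that fell, where a control would lie near 0. For a mixture with control liver RNA, a first test on the genes that fell did not decide: 53.2% implied a control share within 0.2 of their median of 0.149, where under 50% was set to exclude it, so for these genes alone a mixture cannot be told apart from a weaker response. A second test was added after the first had not decided. With 1 mixing share as the whole cause, genes that rose and genes that fell would imply the same share. Their median shares lay at least 0.316 apart with any control array or their mean as the source, against at most 0.162 on the other 7 arrays. Those arrays implied shares of only -0.03 to 0.24, which leaves little room for such a gap, so this reference cannot decide. A mixture, alone or beside a weaker response, stays open. These tests did not take up the place of this array outside all others on the second principal component. Nor did they take up its high level of the combined adipocyte, pancreas, erythroid and muscle list, or the genes that changed more on it than on the other 3. The design names no difference between these mice, and no biological explanation was tested.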

How the results depend on the processing

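Among genes past the threshold in both fits none was opposite in direction under any alternative. Of 2169 alternative values of the 109 named genes past the threshold, 0 were reversed and 1960 stayed past it, and 71 genes stayed past it under all alternatives run. These genes were picked for passing on the same arrays that the alternatives reuse, so reversals were unlikely in advance. The sign of the median of each tested list was followed over the background, scaling, source and offset settings. No called list changed sign. The acute phase list changed sign under 3 of these settings. The glycolysis, xenobiotic metabolism, unfolded protein, oxidative phosphorylation and lysosome lists each changed sign under 1. The sign of other genes was not followed. The number of genes past the threshold was 2610 with array weights, 2381 at a threshold of 0.10 and 775 when a 1.5-fold change was also required. Leaving out 1 array gave 886 to 2261 genes, with 926 without control ASO replicate 2, 944 without control ASO replicate 3, 886 without Mogat1 ASO replicate 3 and 994 without Mogat1 ASO replicate 4; fewer arrays lower the power of the fit. Under the scalings the share of higher calls was 47.9% with median scaling and 53.8% in the result given above. The median change of all genes stayed within 0.02 of 0 under all of them, which aligning the arrays largely fixes in advance. The number of called lists was 10 and fell to 0 with an estimated correlation and to 0 by the exact test, whose adjusted p cannot go below 0.139 here; fry called 8, of which 7 were among the 10, without the NRF2, macrophage and cell cycle lists. Leaving out 1 array gave 9 to 14 called lists. Some lists gained a call: PPAR-alpha targets with median scaling, with no filter, and without control ASO replicate 1, Mogat1 ASO replicate 2 or Mogat1 ASO replicate 3; hepatocyte identity with median scaling and without control ASO replicate 3, control ASO replicate 4 or Mogat1 ASO replicate 1; liver injury with no filter, stricter detection or array weights and without control ASO replicate 4 or Mogat1 ASO replicate 1; bile acid genes with median scaling, stricter detection or fry. Periportal genes gained a call with median scaling, no filter or array weights and without control ASO replicate 4 or Mogat1 ASO replicate 1. Female-biased, cholesterol synthesis and immediate early genes also gained calls under 1 or more alternatives. The NRF2 list lost its call with the mean of all probes and without control ASO replicate 1, Mogat1 ASO replicate 2 or Mogat1 ASO replicate 4; each other list kept its direction and its camera call with the preset correlation under all these settings. With the replicate number as a block 1489 genes passed, of which 1295 were among the 1549, 14 lists were called (the 10 and the PPAR-alpha, hepatocyte, periportal and female-biased lists) and the Mogat1 log2 difference was 0.01. Same-numbered arrays did not all deviate together (correlations of 0.23, 0.07, -0.02 and -0.01), so the numbers did not act as a pairing throughout. The replicate 1 arrays were each other's closest match (0.23), while the highest value, 0.28, joined control ASO replicate 4 and Mogat1 ASO replicate 2. An influence shared by the replicate 1 arrays was not excluded. The Mogat1 probe passed no threshold under any alternative. The cause of the higher count with array weights was not tested. A block for the BeadChip was not run, nor were robust hyperparameters for the lists, which camera does not take. Signal over background limits Mogat1, Mogat2 and other dim probes.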

Other observations

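Several gene groups not described so far held single strong changes. Among 31 lysosome and autophagy genes, 5 rose and 2 fell (adjusted p = 0.312 for the list). The autophagy gene Atg7 was 2.26-fold lower (SE 0.12, adjusted p = 3.6e-04), while Hexa and Laptm5, both of lysosomes, were 1.58-fold (SE 0.11) and 1.51-fold (SE 0.11) higher. Among 12 heat shock genes only Hspb1 passed, 2.78-fold lower (SE 0.26, adjusted p = 0.0046; adjusted p = 0.157 for the list). Among 23 markers of sinusoidal endothelial cells, 2 rose and 1 fell (adjusted p = 0.476 for the list): the hyaluronan receptor genes Lyve1 and Stab2 went opposite ways, Lyve1 2.43-fold higher (SE 0.17, adjusted p = 0.0012) and Stab2 1.48-fold lower (SE 0.10, adjusted p = 0.0043). The pyruvate kinase gene Pkm was 1.71-fold higher (SE 0.12, adjusted p = 0.0034), the 1 of 17 glycolysis genes that passed. The clock gene Clock was 1.53-fold lower (SE 0.12, adjusted p = 0.0084), the 1 of 17 circadian genes that passed.

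Of 30 genes of xenobiotic metabolism 7 rose and 1 fell (adjusted p = 0.738 for the list), led by Gsta1 and Gsta2, with Cyp3a11, a drug-metabolizing enzyme gene, 2.43-fold higher (SE 0.25, adjusted p = 0.0084). Of 25 genes of the unfolded protein and integrated stress response, 1 rose and 2 fell (4 and 3 adjusted over the list alone, adjusted p = 0.902 for the list). Of 23 cholesterol synthesis genes 1 fell, Mvk, which was not detected in the Mogat1 ASO livers (at least 1.48-fold lower, adjusted p = 0.0096). Of 19 genes of phospholipid and sphingolipid synthesis 3 fell, with Sphk2 1.42-fold lower (SE 0.10). In each of the lists for lipoprotein assembly (19 measured), oxidative phosphorylation (41 measured) and the combined adipocyte, pancreas, erythroid and muscle markers (8 measured), 1 gene fell and none rose (0, 0 and 1 fell adjusted over the list alone; adjusted p = 0.538, 0.904 and 0.538). The median and mean log2 difference had unlike signs for lipoprotein assembly (-0.05 and 0.02), oxidative phosphorylation (0.01 and -0.02) and xenobiotic metabolism (-0.04 and 0.16). Over the background, scaling, source and offset settings the median ran from -0.047 to 0.015 for oxidative phosphorylation and from -0.075 to 0.014 for xenobiotic metabolism. Of 20 immediate early genes 1 rose (4 adjusted over the list alone, adjusted p = 0.145), and of 11 cholangiocyte markers none passed. The acyltransferase list had 4 measured members, too few for the test; none passed over all genes, and Dgat1 alone was lower adjusted over the list alone.

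The comparisons of single genes on Mogat1 ASO replicate 1 were chosen after the result was seen. On that array the combined adipocyte, pancreas, erythroid and muscle list had a mean standardized level of 1.31, and the other 7 arrays lay at -0.55 to 0.20. Genes differed in how far that array shared the group change, from 0.01 for Srxn1 to 1.86 for Plin4 among the named genes called at least 2-fold without it. Synj2bp showed 0.99 of the change, Rtn4ip1 1.04, Atg7 1.03, Plin5 1.16 and Cxcl9 1.43. Gsta1 showed 0.45, Gsta2 0.31, Cyp3a11 0.28 and Nqo1 0.14; the call for Nqo1 (adjusted p = 0.0188) ended without control ASO replicate 3 (0.0590), Mogat1 ASO replicate 3 (0.0529) or Mogat1 ASO replicate 4 (0.0605).

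Pairing of the ASO with transcripts other than its target was not tested for any gene that fell, Obp2a, Synj2bp, Immp2l, Rtn4ip1, Atg7, Pdzrn3 and Aatk included, since the oligonucleotide sequence is not given in the sources used here. The folds of these genes are differences between the groups and do not tell a direct action of the oligonucleotide from an effect through Mogat1.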
